A study of Mus musculus with 10 samples.

How the data were processed

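Expression was measured in jejunum, ileum, distal colon, liver and spleen of male ICR mice aged 28 months that had eaten a control diet or the same diet with LB81 yogurt since 8 months of age. Per the labels' protocols, RNA was extracted from each tissue of each mouse, equal amounts were pooled over the 10 yogurt-fed or the 9 control mice, and 100 ng of each pool was amplified, labelled with biotin and measured on a whole-genome mouse expression array from Affymetrix. Each of the 5 tissues therefore had 1 array per diet, 10 arrays in all, and the spread between mice was averaged out before the measurement. The values used are the log2 expression values per probe set that the authors deposited, 45101 probe sets per array including 64 array controls. The submitters' processing notes name MAS5 and affy, with no version and no statement of what each was used for. How the values were summarised and scaled is not given in the sources used here. The design of the tests assumed MAS5 values. The trimmed means of the antilogged values lay between 187 and 207, which does not settle whether the arrays had been scaled to 1 common target, and the array medians lay between 5.42 and 5.50. The log2 ratio of 3' over 5' signal, a sign of RNA quality, was 0.05 to 0.23 for Gapdh and 0.66 to 1.01 for actin on the 6 gut arrays, and those of liver and spleen stand in the report. Nothing further was scaled. No coordinates are given, since no genome build was used.

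Probe sets were named with the platform annotation and, through the Entrez gene number, with the symbols of the RefSeq annotation of mouse assembly GRCm38.p6. A single symbol was given for 34958 probe sets, of which 34754 were matched by gene number, and no symbol differed between the sources. Several symbols were given for 932 probe sets, which were not used, and 9211 were unnamed here. The 18195 genes were each represented by the probe set with the highest mean over the 10 arrays, and the report says where other probe sets of a named gene differed widely. Probe sets ending in x_at or s_at can bind transcripts of related genes.

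For the comparison of diets, values below an array's 50th percentile were raised to that percentile, called the floor, which lay between 5.42 and 5.49. A gene was measured in a tissue if at least 1 of its 2 arrays lay above the floor. The log2 ratio of yogurt over control was then computed per gene, and genes at least 2-fold higher or lower were counted. A ratio against a value at the floor is a lower bound and is given as at least that fold. So is a list's median that falls on such a gene, and other medians take these bounds as they stand. With 1 array per diet in each tissue there are no replicates, so no p-value is given for diet within a tissue. The number of arrays limits the precision of every value. For 47 gene lists, fixed before the data were examined, the median log2 ratio of the measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list with at least 5 measured genes was called outside its range when its median lay below the 2.5 or above the 97.5 percentile. Random lists do not carry the shared regulation of a real list, so more than the 5% expected by chance can fall outside without any effect of diet. The lists hold 919 genes, of which 814 were matched. The list of ileal bile acid handling also holds Guca2a, the gene of the peptide guanylin, which is counted with it throughout. They cover pathways, cell types of the gut, liver and spleen, and cells of other organs that a dissected sample could hold.

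Genes were counted as shared when at least 1.5-fold higher, or at least 1.5-fold lower, in at least 4 of the 5 tissues, and this count was repeated for all 16 ways of swapping the diets within tissues. For the comparison of gut segments, 13605 genes above the floor in at least 2 arrays were fitted with limma (lmFit and eBayes with trend) on tissue and diet over all 10 arrays, with 4 residual degrees of freedom. Values below the floor were raised to it first, so a gene at the floor in a segment shows almost no spread there. Its SE and p-value can then be too small. Genes with a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference were called. All tissues came from the same 2 groups of mice. These p-values measure how far the diet ratio of a gene varied over the 5 tissues, not the spread between mice. The diet term of this fit, tested after the data were seen, asks for a shift common to the 5 tissues. Its p-values measure the spread between tissues of the same mice, so they cannot stand for replicates of the diet.

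The genes named were chosen by a rule fixed before the data were examined. In each tissue the rule took the 8 highest and 8 lowest ratios among genes above the 75th percentile on the brighter array. The probe sets of these genes had to have ratios of 1 sign. It also took the 4 leading members of each list outside its range. To these it added every member at least 2-fold different of 6 lists on antimicrobial defence, immunoglobulins, cytokines, the clock and the pancreas. For the segments it took the 6 largest differences each way and the members of the bile acid, enterocyte and colonocyte lists. Only part of the genes that the rule gives are named in the text. Genes outside the rule are said to be chosen after their values were seen.

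The procedures were tested on simulated data. In a simulated jejunum comparison, 100% of genes raised by log2 1.5 and 0 of 12030 unchanged genes were called 2-fold, a list raised by log2 0.3 reached percentile 100, and 3 of 44 lists with no shift lay outside their range. There every probe set had the same noise, an SD of log2 0.12, and the raised genes were drawn from brighter ones. With so little noise an unchanged gene could hardly reach 2-fold, so these counts give no error rate for the real arrays. In a simulated comparison of jejunum with ileum, limma called 49% of genes changed by log2 1, 100% of those changed by log2 2, and 0 of 13405 unchanged genes. A change of log2 1 is the 2-fold threshold itself, and 88% of the genes so changed had an adjusted p under 0.05 in limma. For a simulated diet term over 5 tissues, 98% of genes raised by log2 1 and 14 of 13405 unchanged genes had an adjusted p under 0.05. The noise there was drawn separately for each array, whereas the real tissues of a diet come from the same mice. These shares are therefore no detection or error rates for the real diet term. Alternatives covered quantile normalization, centring, loess, floors at the 35th and 65th percentile or a pseudocount at the 25th, other choices of probe set, other fold thresholds, limma without trend or diet term, and leaving out arrays and genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.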

Results

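Gene expression was compared between mice fed LB81 yogurt, a milk fermented with Lactobacillus bulgaricus and Streptococcus thermophilus, and mice fed the same purified diet without it. The males, of the outbred ICR stock, were 28 months old and had eaten the diets since 8 months of age, with yogurt at 1 to 2% of the diet. Pooled RNA of 10 yogurt-fed and 9 control mice gave 1 array per diet in each of 5 tissues. The comparison asks what differed between the diets in the gut, liver and spleen of aged mice. Arrays of the same tissue had Spearman correlations of 0.991 to 0.994 across probe sets, and arrays of different tissues 0.858 to 0.978. Because each diet had 1 pool per tissue, no difference between the diets within a tissue has a replicate check, and each is given as a log2 ratio of yogurt over control that describes these arrays. Genes at least 2-fold higher and lower in the yogurt pool numbered 44 and 2 of 12370 measured in distal colon, 40 and 3 of 12280 in jejunum, 23 and 16 of 11883 in spleen, 18 and 6 of 12167 in liver, and 8 and 4 of 12304 in ileum. At 1.5-fold the balance turned in spleen, with 75 higher and 130 lower, and in ileum, with 26 and 36. These 2 tissues also had the lowest median log2 ratios over all measured genes, -0.048 and -0.039, against -0.026 in liver, -0.014 in distal colon and -0.011 in jejunum. The counts at 1.5-fold were not repeated after centring, so a small offset of the whole array cannot be told apart from the diet there. Counts of list members as higher or lower are also taken against 0. Of the 213 list medians, 99 lay outside their matched range, 65 above and 34 below, where 10.65 would by chance if the genes of a list varied independently.

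**Figure D1:**
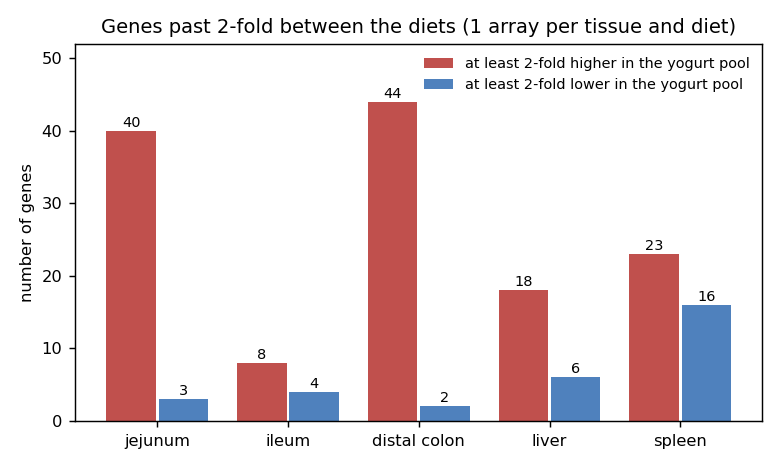
Number of genes at least 2-fold higher (red) or lower (blue) in the yogurt pool than in the control pool, by tissue, from 1 array per tissue and diet. Distal colon with 44 and jejunum with 40 had the most genes on the higher side, and spleen with 16 the most on the lower side.

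The distal colon of the yogurt pool carried far more transcript of secreted antimicrobial proteins. Reg3b, a C-type lectin with antibacterial activity, was at least 34.4-fold higher (log2 ratio 5.10, control at the floor), and its relative Reg3g was at least 5.63-fold higher (2.49). Ang4, an antibacterial ribonuclease of Paneth and goblet cells, was 22.7-fold higher (4.51). Itln1, a lectin that binds microbial sugars, was 7.42-fold higher (2.89), and Pla2g2a, a secreted phospholipase that attacks bacterial membranes, was 4.53-fold higher (2.18). Of 12 measured antimicrobial genes, 11 had a higher value in the yogurt pool and 7 were at least 2-fold higher, with a median of at least 1.26 at percentile 100 of its matched lists. Across the alternatives this median ranged from 0.41 to 2.18. Reg3b, Reg3g, Ang4, Itln1 and Pla2g2a were all at least 8-fold brighter in the control ileum than in the control colon. Saa3, a serum amyloid, was at least 7.70-fold higher (2.95), and the neutrophil calprotectin genes S100a8 and S100a9 were at least 2.85-fold and 2.01-fold higher. A floor at the 65th percentile gave Reg3b, Ang4, Itln1, Saa3, Reg3g and S100a8 log2 ratios of 3.88, 3.44, 2.04, 1.72, 1.27 and 0.28. S100a9, at 6.49 in the yogurt pool and 4.91 in the control pool, lay below that floor.

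Genes of bile acid handling and xenobiotic metabolism were also higher in distal colon, while the enterocyte list lay within its range (median 0.07, 7 of 13 higher). Among the largest single ratios were the following. Tmigd1, a brush border adhesion protein, was 8.37-fold higher (3.07), Sptssb, a subunit of serine palmitoyltransferase, at least 11.9-fold (3.57), and Ces1g, a carboxylesterase, at least 10.1-fold (3.34). B4galnt2, a glycosyltransferase, was 7.75-fold higher, but its 3 probe sets ranged from 0.25 to 2.95. All 6 measured members of the ileal bile acid list, Guca2a among them, were higher (median 0.41). They included Slc51a, a basolateral bile acid exporter, at least 3.16-fold, its partner Slc51b, 1.66-fold, and the carrier Fabp6, 1.49-fold. The xenobiotic list had 8 of 9 members higher (median 0.38), led by Cyp2e1 at 4.15-fold, Cyp2c55 at 3.56-fold and Ugt2b5 at a log2 ratio of at least 2.00, but its median was -0.0019 with a pseudocount in place of the floor. Fatty acid oxidation genes were higher in 19 of 21 cases (median 0.16), with Acaa1b, a peroxisomal thiolase, at least 3.99-fold. The log2 ratios at a 65th-percentile floor of Sptssb, Ces1g, Cyp2e1, Ugt2b5, Acaa1b and Slc51a were 2.35, 2.12, 1.32, 0.77, 0.77 and 0.43. Of the 44 genes, 23 were at least 8-fold brighter in the control ileum than in the control colon, and 21 remain without them, a comparison chosen after the values were seen. The distal position markers Hoxb13, Hoxd13, Hoxa13 and Hoxd10 had ratios of -0.25, -0.24, -0.31 and 0.04, with Hoxa13 close to the floor, values looked up as a check of where the tissue was taken.

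Proliferation and lymphocyte genes also differed in distal colon. Of 25 cell cycle genes, 22 were higher (median 0.36, percentile 100), with Ccna2, a cyclin of S phase, 1.89-fold and Aurkb, a mitotic kinase, 1.44-fold higher. All 6 measured cytotoxic cell genes were higher (median 0.37), led by the chemokine Ccl5 at 1.54-fold and the granzyme Gzmk at 1.45-fold. Of 21 interferon-stimulated genes, 17 were higher (median 0.24), with Cxcl9, a chemokine for T cells, at 1.79-fold (log2 ratio 0.37 with the floor at the 65th percentile), Iigp1 at 1.61-fold and Ifit1 at 1.60-fold. Goblet cell genes were higher in 16 of 18 cases (median 0.11), including the mucin Muc2 at 1.34-fold, and enteroendocrine genes in 8 of 11 (median 0.19). On the lower side were B cell genes (13 of 15, median -0.14), matrix genes (18 of 22, median -0.11), cholesterol synthesis genes (16 of 19, median -0.09) and senescence-associated genes (7 of 9, median -0.18), the latter with the cell cycle inhibitor Cdkn1a at -0.28.

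Markers of fat and muscle of the gut wall differed alongside these groups in distal colon. Adipocyte genes were higher in 6 of 7 cases (median 0.73), with the hormone gene Adipoq at least 4.26-fold, Car3 3.93-fold and the lipase Lpl 3.08-fold higher. All 17 smooth muscle genes were lower (median -0.28), including Smtn at -0.46 and Lmod1 at -0.38. Clock genes were lower (median -0.20), with Ciart, a repressor of the clock, at -1.01 and the transcription factor Dbp at -0.76. Adipoq had a log2 ratio of 0.86 and Ciart -0.52 with the floor at the 65th percentile. The carbonic anhydrase Car1 of colonocytes was higher (1.32), and Igkv6-14, an immunoglobulin segment, was lowest at -1.07. Of the 44 genes higher in the yogurt pool, 18 had a control value at the floor, so their folds are lower bounds. The neutrophil (at least 0.17), heat shock (0.06), T cell (0.08), erythroid (0.11), exocrine pancreas (-0.13) and hepatocyte (-0.28) medians also lay outside their ranges, the last 4 of these only under part of the alternatives. The erythroid median was -0.07 with the floor at the 35th percentile and -0.11 with a pseudocount.

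**Figure D2:**
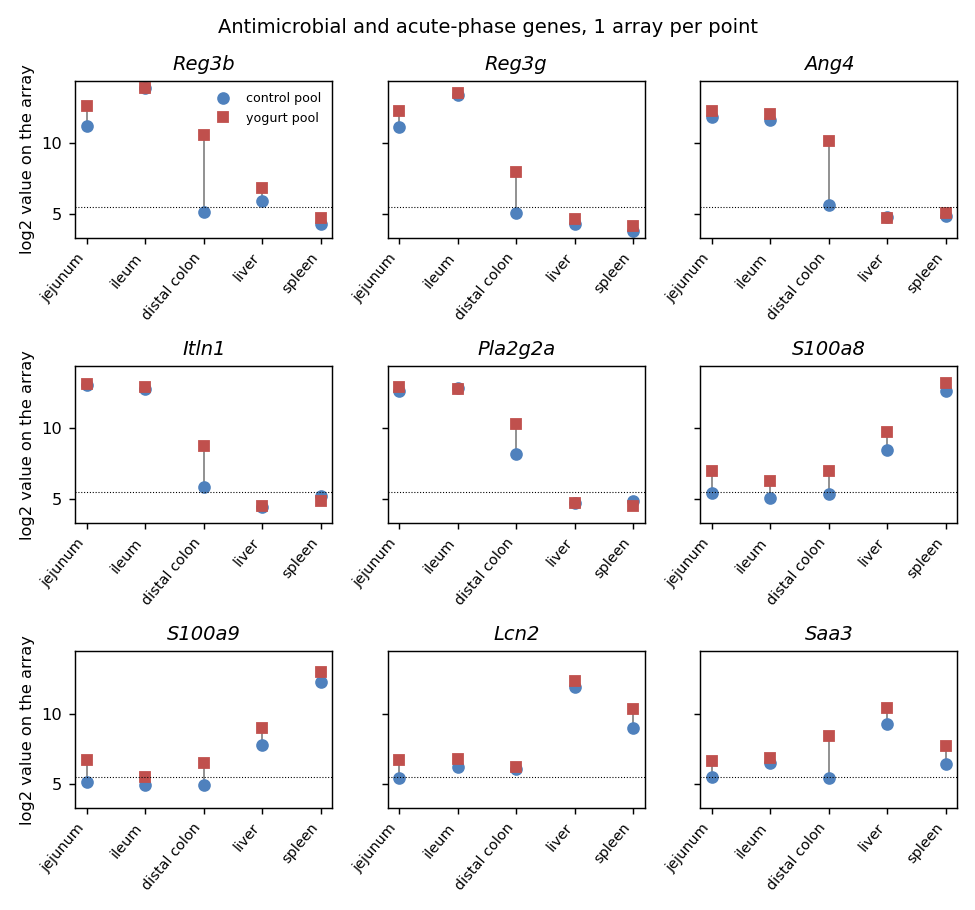
Log2 value on each array for 9 antimicrobial and acute-phase genes (vertical axes) in the 5 tissues, with the control pool as a circle, the yogurt pool as a square, and 1 array per point. The dotted line marks the highest floor, 5.49, and the gap for Reg3b in distal colon runs from 5.10 to 10.59.

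In jejunum the largest group was that of pancreatic digestive enzymes. All 18 measured exocrine pancreas genes were higher in the yogurt pool and 16 were at least 2-fold higher (median 1.47, percentile 100). Examples are Cuzd1, a zymogen granule protein, at 5.28-fold (2.40), the lipase relative Pnliprp1 at 3.53-fold, the granule membrane protein Gp2 at 3.34-fold and the ester lipase Cel at 3.20-fold. Outside that list, Reg2, a secreted protein of regenerating islets and acini, was 8.04-fold higher (3.01), the trypsinogen Prss3 at least 6.60-fold, the pancreatic serpin Serpini2 at least 6.75-fold and the insulin gene Ins2 3.96-fold, with log2 ratios of 1.59, 1.62 and 1.30 for the last 3 when the floor was at the 65th percentile. Without the exocrine and islet genes, a comparison chosen after the values were seen, 23 of the 40 genes remain, and they still include the pancreatic genes Reg2, Prss3 and Serpini2. Of the 10 measured gastric genes, a list also chosen after the values were seen, all were lower (median -0.44). Among them were gastrin (Gast, -1.47) and the gastric trefoil factor Tff1 (-0.66).

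Antimicrobial genes were higher in jejunum as well. Of 13 measured, 12 were higher and 6 at least 2-fold higher (median 0.65, percentile 100), in the same array as the pancreatic genes. Among jejunal genes above the floor on both arrays, the largest ratio belonged to the Paneth cell defensin Defa31, 15.4-fold (3.95), whose probe set can bind several near-identical defensin transcripts. Reg3b was 2.62-fold and Reg3g 2.20-fold higher, and S100a8, S100a9 and the siderophore-binding Lcn2 were at least 2.79-fold, 2.31-fold and 2.28-fold higher. With the floor at the 65th percentile the last 3 had log2 ratios of only 0.35, 0.07 and 0.06. Retnlb, a goblet cell protein, was lower at -0.87. Antigen presentation genes were slightly higher, 9 of 10 for class II (median 0.23) with H2-DMa at 0.35 and H2-Eb1 at 0.31, and 8 of 10 for class I (median 0.11). So were macrophage genes (15 of 16, median 0.12), matrix genes (19 of 22, median 0.16), smooth muscle genes (16 of 17, median 0.16) and plasma cell genes (14 of 19, median 0.08).

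Genes of digestion, gut hormones and oxidative or drug metabolism were lower in jejunum by small amounts, while the goblet (0.03), tight junction (-0.03) and crypt stem cell (-0.02) medians lay within their ranges. Of 23 genes of digestion and absorption, 21 were lower (median -0.12), among them the lactase gene Lct at -0.51 and the glucose transporter Slc2a2 at -0.39. Enteroendocrine genes were lower in 11 of 12 cases (median -0.27), with ghrelin (Ghrl) at -0.53, Gip at -0.47, somatostatin (Sst) at -0.44 and Cck at -0.41. On the same 2 arrays gastric genes were lower (median -0.44) and exocrine pancreas genes higher. A difference in where the jejunum was taken therefore cannot be told apart from the diet here. All 6 measured members of the ileal bile acid list, Guca2a among them, were lower (median -0.27). Of these, Nr0b2 hardly differed, at log2 values of 6.933 in the yogurt pool and 6.937 in the control pool. Fabp6, Slc10a2 and Fgf15 stood at the floor in both pools and were not measured. Also lower were 9 of 10 xenobiotic genes (median -0.22) and 18 of 21 Nrf2 and glutathione genes (median -0.20). So were 15 of 21 fatty acid oxidation genes (median -0.13) and 24 of 27 oxidative phosphorylation genes (median -0.08). Leading members were the drug-metabolising Cyp2b10 at -0.74, the efflux pump Abcb1a at -0.78 and the epoxide hydrolase Ephx1 at -0.56. Clock genes were lower in 14 of 18 cases (median -0.20), with Per3 at -0.52 and Usp2 at -0.51. The acute phase (0.27), neutrophil (0.15), cytotoxic (0.12), colonocyte (0.09), immediate early (0.06) and heat shock (0.05) medians lay above their ranges, and of these only heat shock did so under every alternative. The bile acid and oxidative phosphorylation medians did not lie outside under every alternative either.

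The ileum had the fewest genes past 2-fold. Pla2g4c, a cytosolic phospholipase, had the largest ratio there among genes above the floor on both arrays, 15.6-fold (3.96), although its other probe set gave 0.47 and the mean of both 2.22, followed by the keratin Krt78 at 7.49-fold (2.90). Adipocyte genes were higher in 6 of 8 cases (median 0.59, percentile 100), with Car3 at 3.40-fold, Adipoq at 2.78-fold, Retn at 1.77-fold and Fabp4 at 1.60-fold. Reg1, a secreted protein of pancreas and gut, was lower (-1.78), as were Car1 (-1.27), the metallothionein Mt2 (-0.99), Cyp2c55 (-0.98) and the glucose-6-phosphatase G6pc (-0.91). Adipoq, Retn and Reg1 had log2 ratios of 0.73, 0.34 and -1.14 with the floor at the 65th percentile. Acute phase genes were higher in 7 of 10 cases (median 0.33), with Saa2 at 1.84-fold. The antimicrobial median was 0.07, with Ang4 at 0.46 and Reg3b at 0.01. MHC class II genes (7 of 9, median 0.17, H2-Eb1 at 0.52), smooth muscle genes (17 of 17, median 0.15), macrophage genes (12 of 17, median 0.11) and cytotoxic genes (7 of 8, median 0.19) were higher. All 19 cholesterol synthesis genes were lower (median -0.12), as were 18 of 20 Nrf2 and glutathione genes (median -0.12) and 19 of 21 fatty acid oxidation genes (median -0.10). Clock genes were lower in 14 of 18 cases, with a median within its range (-0.11). The neutrophil (0.15), heat shock (0.10), matrix (0.07), liver tumour (0.05) and cell cycle (0.02) medians lay above their ranges by small margins. Those of the antimicrobial, neutrophil, matrix and cholesterol lists did not lie outside under every alternative.

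In liver, genes of myeloid cells and of the acute phase were higher in the yogurt pool. All 14 measured neutrophil genes were higher (median 0.37, percentile 100), with Chil3, a chitinase-like protein, 2.60-fold, S100a8 2.41-fold and S100a9 2.38-fold higher. The endotoxin co-receptor Cd14 and the B cell chemokine Cxcl13 had log2 ratios of 1.32 and 1.33. Of 24 acute phase genes, 22 were higher (median 0.16), led by Saa3 at 2.19-fold and the orosomucoid Orm2 at 2.05-fold, and Reg3b was 1.96-fold higher (log2 ratio 0.35 with the floor at the 65th percentile), with an antimicrobial median of 0.38. All 16 measured cell cycle genes were higher (median 0.30), with Ccna2, Mki67 and Top2a at 0.52, 0.48 and 0.48, and so were 15 of 19 tumour-associated genes (median 0.14), with Spink1 at 0.74. Immunoglobulin genes were lower, the IgA heavy chain Igha at -1.56 and the joining chain Jchain at -0.95, although the plasma cell list as a whole lay within its range at -0.06. The 2 liver arrays had the highest log2 ratios of 3' over 5' actin signal of the 10, 1.82 for yogurt and 2.01 for control, with 0.86 and 0.98 for Gapdh.

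Liver lipid metabolism also differed. Lipogenic genes were higher in 14 of 19 cases (median 0.12), with the elongase Elovl6 at 2.03-fold, the lipid droplet protein Pnpla3 at 1.92-fold and fatty acid synthase Fasn at 1.70-fold. Cholesterol synthesis genes were lower in 17 of 19 cases (median -0.22), including Msmo1 at -0.60 and squalene epoxidase Sqle at -0.56. Bile acid genes were lower in 15 of 18 cases (median -0.16), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.82, Cyp7b1 at -0.53 and Cyp8b1 at -0.49, while Cyp39a1, another bile acid hydroxylase, was 3.11-fold higher (1.64). Fatty acid oxidation genes were lower in 20 of 24 cases (median -0.13), with Acot1 at -0.82. The steroid hydroxylase Cyp17a1 had the highest ratio in liver among genes above the floor on both arrays, 4.44-fold (2.15, and 1.42 with the floor at the 65th percentile). Sex-biased liver genes were lower in 9 of 12 cases (median -0.16), with the male-biased Elovl3 and Hsd3b5 both at -0.55. The clock median, -0.35 over 17 genes, was the lowest of the 5 tissues, with Ciart at -1.03 and Dbp at -0.86 against the activator Arntl at 0.67. The 3' over 5' actin log2 ratios of the same 2 arrays, 1.82 for yogurt and 2.01 for control, stand beside these values too.

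Of the other cell types in liver, smooth muscle genes were lower in 8 of 11 cases (median -0.14) and exocrine pancreas genes higher in 7 of 8 (median at least 0.16). The MHC class II (0.12), macrophage (0.08), interferon (0.06), matrix (0.04), Nrf2 (0.04), heat shock (0.03), bile acid uptake (0.22) and colonocyte (0.11) medians lay above their ranges, and that of immediate early genes (-0.12) below. The class II, macrophage, heat shock, bile acid uptake and colonocyte medians did not do so under every alternative. Of the 18 genes at least 2-fold higher, 3 had a control value at the floor.

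The spleen of the yogurt pool held more transcript of neutrophil granule genes. All 16 measured genes of neutrophils and their precursors were higher and 8 were at least 2-fold higher (median 1.01, percentile 100). The primary granule proteases Prtn3 and Ctsg were 3.74-fold (1.90) and 3.37-fold (1.75) higher, and the peroxidase Mpo 3.21-fold (1.68), while Lcn2 was 2.55-fold and Camp, an antimicrobial cathelicidin, 1.95-fold higher. Mast cell genes were higher in 7 of 7 cases (median at least 0.60), with the chymase Cma1 at 1.44 and the carboxypeptidase Cpa3 at 1.15. Platelet lineage genes were higher in 14 of 14 cases (median 0.33), including Vwf at 0.44 and Itga2b at 0.37, and erythroid genes in 11 of 14 (median 0.14). The spleen transcript BC018473 was 9.89-fold higher (3.31) and Slfn4, a schlafen of myeloid cells, 2.80-fold. For BC018473 a floor at the 65th percentile gave a log2 ratio of 2.36. The yogurt spleen array also had the highest log2 ratio of 3' over 5' Gapdh signal of the 10 arrays, 1.29 against 1.01 for control, and a lower trimmed mean, 187 against 194. For actin the log2 ratio was 1.09 in the yogurt spleen pool and 1.01 in the control pool.

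Plasma cell and macrophage genes were lower in spleen, while the B cell (-0.05) and T cell (-0.03) medians lay within their ranges. Rgs13, a regulator of germinal centre B cells, was at least 8.40-fold lower (-3.07, yogurt at the floor, and -2.04 with the floor at the 65th percentile), the IgE receptor Fcer2a of B cells had a ratio of -1.19 and the T cell checkpoint receptor Ctla4 -1.20. Plasma cell genes were lower in 17 of 19 cases (median -0.30), with the syndecan Sdc1 at -0.67, although another of its probe sets gave -0.01, and the transcription factor Irf4 at -0.56. Macrophage genes were lower in 20 of 21 cases (median -0.21), with Itgax at -0.69 and the complement gene C1qc at -0.61. The chemokine Ccl8 (3.12-fold lower) and the alarmin Il33 (2.14-fold lower) were among the lowest, MHC class II genes were lower in 9 of 10 cases (median -0.18), and immediate early genes in 17 of 21 (median -0.24), with Egr2 at -0.97. Matrix genes were lower in 18 of 21 cases (median -0.16). Rps27 had a ratio of -1.54, whereas the ribosomal protein list lay within its range at 0.02. These lower genes come from the same 2 arrays, with 3' over 5' Gapdh log2 ratios of 1.29 and 1.01.

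Clock genes were lower in spleen in 14 of 15 cases, with a median within its range (-0.14). The remaining spleen lists outside their ranges were the antimicrobial list (0.66, 6 genes that are largely neutrophil genes), goblet (0.26), liver tumour (0.08), cytotoxic (0.07), cell cycle (0.06) and heat shock (0.03) above, and cholesterol synthesis (-0.18), IgA induction (-0.16) and inflammatory cytokines (-0.14) below. The goblet, tumour, cytotoxic, heat shock, cholesterol, IgA, cytokine and immediate early medians did not lie outside under every alternative. With a pseudocount in place of the floor, 8 genes instead of 16 were at least 2-fold lower.

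**Figure D3:**
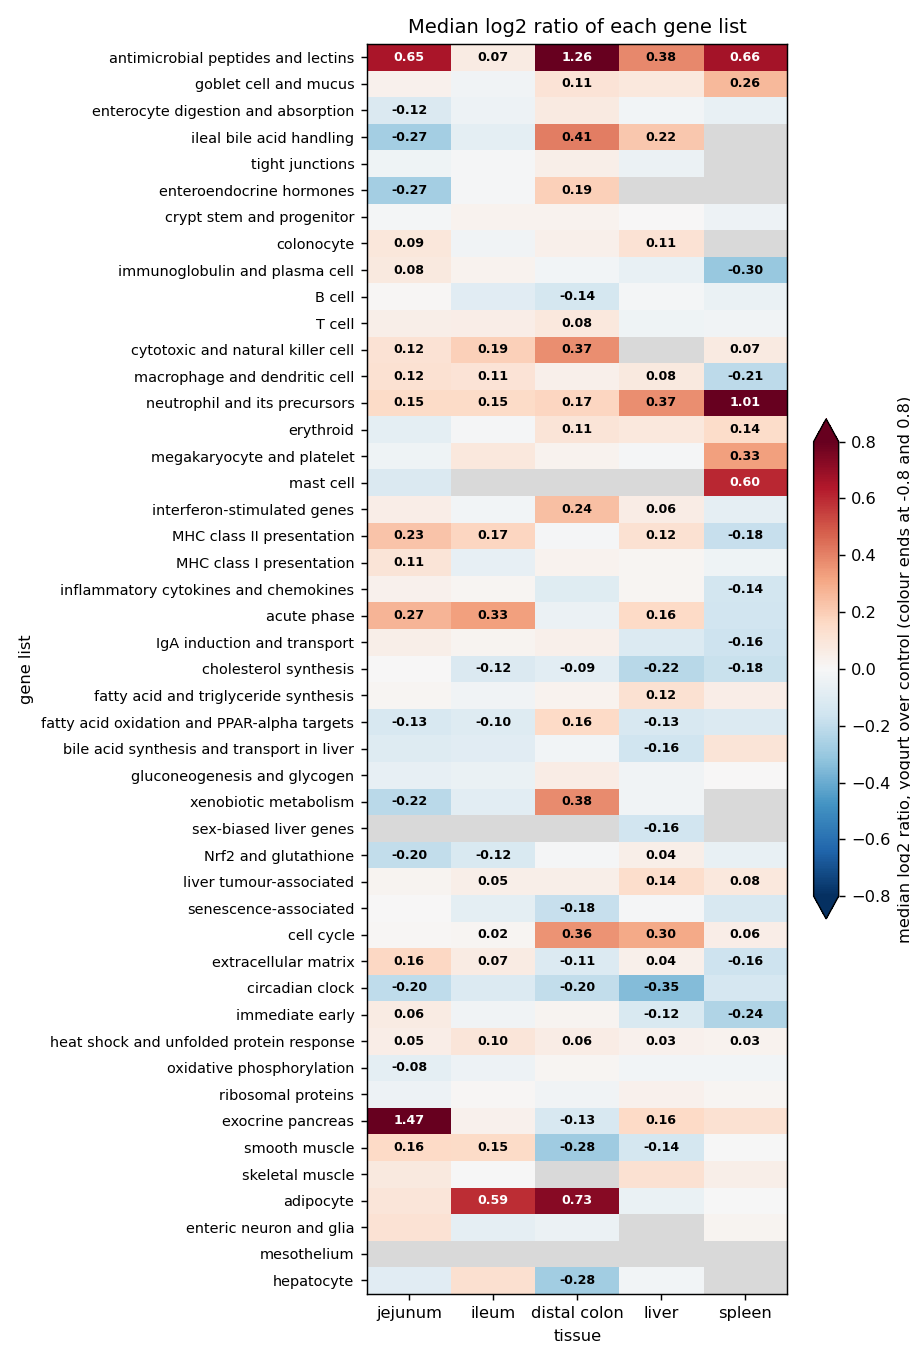
Median log2 ratio of yogurt over control (colour, red higher and blue lower in the yogurt pool) for 47 gene lists (vertical axis) in 5 tissues (horizontal axis). Numbers mark medians outside the central 95% of matched random lists, such as 1.47 for exocrine pancreas in jejunum and 1.01 for neutrophil genes in spleen, and grey marks lists with fewer than 5 measured genes.

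A few genes differed the same way across tissues. At 1.5-fold in at least 4 tissues, 4 genes were higher and 2 lower, of 11489 measured in at least 4. S100a8 was higher in all 5, by 0.59 in spleen and 1.27 in liver, and by at least 0.79, 1.48 and 1.51 in ileum, jejunum and distal colon, where the control was at the floor. Saa3 had a median of 1.13 and a ratio of at least 2.95 in distal colon, S100a9 had a median of at least 1.00, with a ratio of at least 0.03 in ileum, where the control was at the floor and the yogurt value just above it, and BC018473 had a median of at least 1.40, with the control at the floor in every tissue but spleen. The lower genes were Mid1, a ubiquitin ligase, with a median of -0.87, and Cirbp, an RNA-binding protein induced by cold, with a median of -0.69 and -1.16 in spleen. With the floor at the 65th percentile 1 gene met the criterion instead of 6. In limma, the diet term of the fit over all 5 tissues, added after the data were seen, called 0 of 13605 genes at a Benjamini-Hochberg adjusted p under 0.05, and 1445 had an unadjusted p under 0.05. Its adjusted p was 0.116 for Mid1 (-0.90, SE 0.10), S100a8 (at least 1.13, SE 0.14) and Cirbp (-0.73, SE 0.09). It was 0.244 for BC018473, 0.261 for S100a9 and 0.316 for Saa3. Over the 10 pairs of tissues the diet ratios correlated across genes at -0.062 (jejunum and spleen) to 0.268 (jejunum and ileum, Pearson), and genes are not independent replicates.

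**Figure D4:**
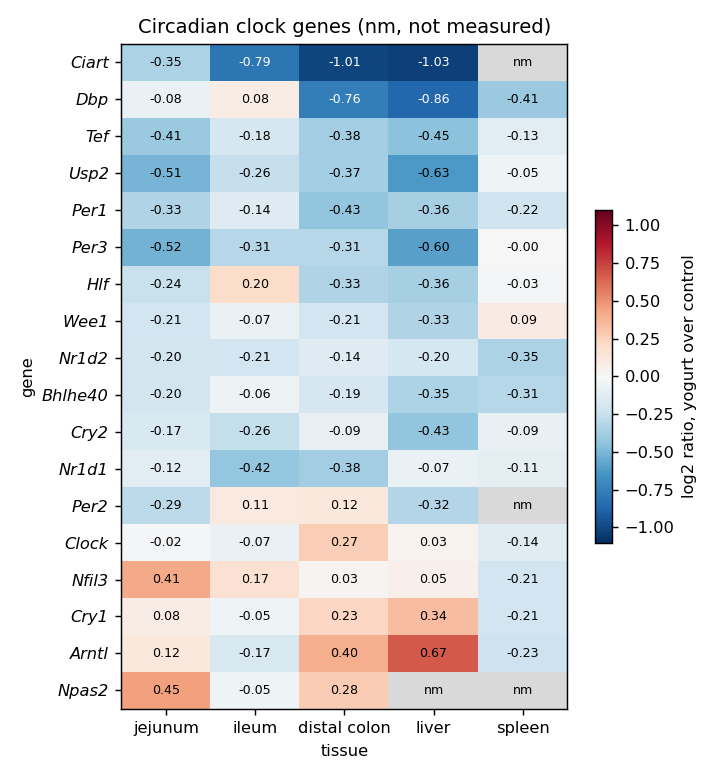
Log2 ratio of yogurt over control (colour and number) for the circadian clock genes (vertical axis) in 5 tissues (horizontal axis), from 1 array per tissue and diet. Ciart was at -1.01 in distal colon and -1.03 in liver, while the activator Arntl was at 0.40 and 0.67 there.

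Differences between gut segments could be tested over both pools of a segment. In limma with Benjamini-Hochberg adjustment, 307 genes were higher and 365 lower in jejunum than in ileum. Fabp6, the ileal bile acid carrier, was at least 326-fold lower in jejunum (log2 difference -8.35, SE 0.15, adjusted p = 3.48e-08, n = 2 pools each). The bile acid transporter Slc10a2 was at least 36.9-fold lower (-5.21, SE 0.12, adjusted p = 1.21e-07), and the hormone Fgf15 at least 12.6-fold lower (-3.65, SE 0.06, adjusted p = 3.53e-08). Of 10 members of the bile acid list 7 were lower, Guca2a among them, 1 was higher and 2 were not called, also when adjusted over the list alone. Among 23 enterocyte genes 9 were higher, 5 lower and 9 not called, with the same counts adjusted over the list alone. Lactase (Lct) was at least 27.2-fold higher (4.76, SE 0.14, adjusted p = 3.68e-07) and Fabp1 26.2-fold higher (4.71, SE 0.07, adjusted p = 1.55e-08), whereas the protease Mep1a was 32.5-fold lower (-5.02, SE 0.15, adjusted p = 5.23e-07). The gastric gene Gkn3 was at least 199-fold (7.64, SE 0.11, adjusted p = 1.55e-08) and the pancreatic elastase Cela2a at least 139-fold higher (7.12, SE 0.30, adjusted p = 2.6e-06), so both jejunum pools carried stomach and pancreas transcripts. Of 14 colonocyte genes 2 were higher, 4 lower and 8 not called, with Car2 14.2-fold higher and Saa1 at least 49.4-fold lower (log2 differences 3.82 and -5.63), and the same counts adjusted over the list alone.

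Between distal colon and ileum, limma with Benjamini-Hochberg adjustment called 664 genes higher and 542 lower in colon, and after quantile normalization 594 higher and 611 lower, so which side held more genes depended on the scaling. Genes of absorption were among those lower. Of 23 enterocyte genes 21 were lower and 2 not called, and of 10 bile acid genes 8 were lower and 2 not called, both unchanged in number when adjusted over the list alone. Apoa1, the main apolipoprotein of high-density lipoprotein, was at least 339-fold lower (-8.41, SE 0.05, adjusted p = 1.37e-10, n = 2 pools each), and Cubn, an endocytic receptor for vitamin B12, at least 86.5-fold lower (-6.43, SE 0.07, adjusted p = 3.52e-09). Reg3g was at least 108-fold lower (-6.75, SE 0.56, adjusted p = 4.23e-05, 1 of its 2 colon values at the floor) and Defa31 449-fold lower (-8.81, SE 0.95, adjusted p = 0.000156), both with large errors. The error of Defa31 came mainly from jejunum, with a diet ratio of 3.95 there against -0.35 in distal colon and -0.002 in ileum. On the higher side, Hoxb13, a positional gene of the distal gut, was at least 72.2-fold higher (6.17, SE 0.09, adjusted p = 7.7e-09), the secreted protein Wfdc2 89.2-fold (6.48, SE 0.19, adjusted p = 2.07e-07), and the water channel Aqp8 at least 40.9-fold (5.35, SE 0.14, adjusted p = 1.03e-07). Of 14 colonocyte genes 8 were higher and 6 not called, also when adjusted over the list alone. The p-values rest on 4 residual degrees of freedom over 10 arrays and on pools of mice that differ in diet. Where a fold in either segment comparison is given as at least that fold, values of 1 segment stood at the floor. This can make the SE and p-value too small.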

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

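Apart from the first test of small-intestinal RNA and the test of colon position, the tests in this part were chosen after the results they bear on had been seen.

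Of the 44 genes at least 2-fold higher in the distal colon of the yogurt pool, 23 were enriched in ileum, so small-intestinal RNA in that pool was weighed. The bounds set beforehand were met on neither side, with a median implied ileal share of 1.09% over 129 ileum-enriched genes and 36.4% of the 44 genes brighter there than on all 4 small-intestinal arrays. Such RNA would bring its abundant transcripts along. However, 10 of the 20 most abundant ileum-enriched genes implied a share more than 10 times below the 12.5% that the raised ones needed at the median. Apoa1 stood at -0.056%, Lgals2 at 0.026% and Naaladl1 at 0.049%, against at least 2.00% for each raised one, which argues against such RNA. Another 6 of the 20 lay less than 2 times below that median or above it, such as B4galnt2 at 22.1% and Pla2g2a at 14.0%. All of these but Clca4a (8.70%) were themselves raised genes that set the median, so they are no separate check. Sampling nearer to the proximal colon remains a candidate explanation, since Hoxb13, Hoxd13, Hoxa13 and Hoxd10, genes of distal position, had a median log2 ratio of -0.25, at percentile 0.13 of matched random lists. These are 4 genes, under the 5 required of the other lists, and Hoxa13 lay close to the floor. The shift was small, with Hoxb13 at a log2 value of 11.52 in the yogurt pool and 11.78 in the control pool. An effect of the diet stays open and untested, because each diet had 1 pool.

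Of the exocrine pancreas genes in jejunum, 88.9% were at least 1.5-fold higher in the yogurt pool, and both pools carried these transcripts far above the ileum. Pancreatic tissue in the yogurt jejunum pool is a candidate source. The 6 measured islet genes had a median of 0.03 at percentile 71.55, with Ins2 at 1.99, Iapp at 0.49 and Gcg at -0.22. Gcg and Scg2 had log2 values of 11.1 and 8.46 in the control ileum, where the pancreatic elastase Cela2a was at the floor. Gut tissue alone thus carried such genes, so their median could not weigh against pancreatic tissue, and the test left it open. Gastric genes were lower in 10 of 10 cases in the same pool (median -0.44). An effect of the diet stays open and untested.

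Clock genes lay below their range in jejunum, distal colon and liver of the yogurt pools, and in ileum (-0.11, 14 of 18 lower) and spleen (-0.14, 14 of 15 lower) within it, though the clock output genes alone lay below theirs in ileum too (-0.20, percentile 0.08). That the 2 diets' mice were sampled at different clock times would move output genes and positive-arm genes in opposite directions, which held in 3 of 5 tissues, too few of them to decide. The positive-arm medians of jejunum (0.12), ileum (-0.05) and spleen (-0.21) lay within their matched ranges, so their signs say little either way. That body temperature at sampling differed is a candidate explanation, since cold-induced genes had a negative and heat-induced genes a positive median in 5 of 5 tissues. The heat-induced median in distal colon (0.06, 4 of 10 lower) lay within its matched range, the cold-induced list had only Cirbp and Srsf5 measured, and Cirbp had been seen to be lower before the test. The heat shock list had also been seen above its range in all 5 tissues, so neither part of this test was new support. The explanations by clock time and by temperature were not tested against each other. An effect of the diet stays open and untested.

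For the 6 genes 1.5-fold different the same way in at least 4 tissues, the 16 ways of swapping diets within tissues, of which 1 is the real one, were too few for a share under 0.05. The highest count among the other ways was 5.

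Some results had opposite signs between tissues, and these differences were not tested. The gap between distal colon and jejunum was 0.679 for ileal bile acid genes (0.41 and -0.27), 0.458 for enteroendocrine genes (0.19 and -0.27) and 0.595 for xenobiotic genes (0.38 and -0.22). That between jejunum and spleen was 0.413 for MHC class II genes (0.23 and -0.18) and 0.326 for matrix genes (0.16 and -0.16). Smooth muscle genes differed by 0.441 between jejunum (0.16) and distal colon (-0.28), and the single gene Car1 by 2.59 between distal colon (1.32) and ileum (-1.27).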

How the results depend on the processing

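The alternatives that left out pancreatic or ileum-enriched genes and the diet term over all tissues were chosen after the data had been seen, and the others beforehand. At a 1.5-fold threshold, genes higher and lower in the yogurt pool numbered 78 and 30 in jejunum, 26 and 36 in ileum, 117 and 11 in distal colon, 61 and 41 in liver, and 75 and 130 in spleen. At a 3-fold threshold they numbered 17 and 0, 3 and 1, 29 and 0, 3 and 0, and 5 and 2 in the same order. With at least 2 measured probe sets, all past 2-fold, they numbered 7 and 0, 1 and 0, 8 and 0, 2 and 1, and 0 and 0, since fewer genes could qualify. With the floor at the 65th percentile, 4 genes were higher in ileum, 1 was lower in distal colon, 11 were higher and 3 lower in liver, 14 were higher and 10 lower in spleen, and 1 was shared by at least 4 tissues. Quantile normalization, centring and loess each left 1 gene lower in distal colon, and a pseudocount 0. With the pseudocount 8 genes were lower in spleen, and 70.4% of the genes past 2-fold there were higher, against 59.0%. Without the exocrine and islet lists 23 genes, Reg2, Prss3 and Serpini2 among them, were higher in jejunum, and without genes 8-fold brighter in the control ileum 21 were higher in distal colon. Shared genes numbered 3 in all 5 tissues, and 3 each in all 4 tissues other than distal colon, liver or spleen. The diet term of the limma fit over all 5 tissues called 0 genes at 1.5-fold and 0 at any fold, with 1445 at an unadjusted p under 0.05. The called lists were 99, of which 70 lay outside their range under every alternative run and 29 did not. The erythroid median in distal colon was reversed to -0.070 (floor at the 35th percentile) and -0.11 (pseudocount), that of xenobiotic genes in distal colon to -0.0019 (pseudocount), and Hamp2 in jejunum to -0.085 without x_at and s_at probe sets. Of 169 named values past 1.5-fold, 131 stayed past it under every alternative run. An alternative under which a gene was no longer measured, or a list had too few measured genes, was left out of these counts. S100a9 in distal colon, below the floor at the 65th percentile, thus counts as kept, so both counts of kept results are upper bounds. Leaving out single arrays, the segment comparisons called 674 to 704 genes between jejunum and ileum, against 672, and 1203 to 1284 between distal colon and ileum, against 1206. Quantile normalization turned the split of the latter from 664 higher and 542 lower to 594 and 611. The lone array of a segment is then assumed to vary like the others. Apart from thresholds and the probe set requirement, the cause was not tested. Values near the floor limit the ratios of dim genes. No paired analysis was possible within a tissue, because each diet had 1 pool there and the 2 pools held different mice. The diet term over the tissues, given above, pairs the arrays by tissue.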

Other observations

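The tests in this part were planned beforehand, and the values singled out were chosen after they were seen. Lists for which no tissue with enough measured genes lay outside its range were those of tight junctions, crypt stem cells, gluconeogenesis, ribosomal proteins, skeletal muscle, and enteric neurons and glia. Crypt stem cell genes had medians from -0.04 in spleen to 0.03 in distal colon, and tight junction genes from -0.05 in liver to 0.05 in distal colon. The mesothelium list had too few measured genes in every tissue.

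Immune cell genes also differed between gut segments, tested with limma and Benjamini-Hochberg adjustment. Of 16 B cell genes, 12 were higher in distal colon than in ileum and none lower, also when adjusted over the list alone. T cell genes were not called in either comparison, 0 of 15 in each. Antimicrobial genes were lower in distal colon than in ileum in 8 of 15 cases and higher in 1, also when adjusted over the list alone. Of 19 cholesterol synthesis genes, 7 were lower in jejunum than in ileum and 0 higher, and 5 were lower in distal colon, with the same counts adjusted over the list alone.

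Between jejunum and distal colon, 10 genes were at least 1.5-fold higher in the yogurt pool in both, where 0.430 would be if the calls were independent, among them Reg3b, Reg3g, S100a8, S100a9, Saa3 and Car3. Between liver and spleen 10 genes were higher in both, where 0.180 would be. The pools came from the same mice, so the tissues are not independent.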
